A study of Mus musculus with 9 samples.

How the data were processed

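Single cells from mouse kidney were measured in 9 samples, which came from 7 libraries of RNA and 2 records of surface antibodies. CD11b+ cells came from 3 quiescent (uninjured) mice and from 2 mice at day 6 after BIRI, an injury treatment whose abbreviation the labels do not spell out. CD45+ cells came from 2 libraries at day 1 after BIRI and were run as CITE-seq, an assay in which antibodies carrying DNA tags are counted in the same droplets as the RNA. Groups and replicate numbers were taken from the titles. The day 6 library numbered 2 in its title carries the number 1 in its library name, and it is called day 6 library 2 here. Other samples that the series design mentions (day 28, spatial data) were not analysed here.

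The deposited values are counts of unique molecular identifiers (UMIs) per gene or antibody and droplet barcode, not normalized, in matrices of the barcodes that the authors kept as cells. Per the labels, libraries were made with 3' Chromium gene expression chemistry. Per the submitters' processing notes, Cell Ranger 6.0 and Space Ranger 1.2.2 were used with the mouse build mm10. Whether intronic reads were counted is not given in the sources used here. The matrices of day 1 and of the other groups list different genes: 32285 against 31053, of which 30406 symbols were shared and kept, while 1879 and 647 occurred in one annotation and were left out. The day 1 matrices also hold 102 antibodies, 7 of them isotype controls that bind no mouse target.

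The deposited barcodes numbered 1832, 1392 and 2599 in quiescent libraries 1, 2 and 3, 8971 and 10049 in day 1 libraries 1 and 2, and 4026 and 3620 in day 6 libraries 2 and 3. The total counts per library were 13137379, 9845074 and 13813997 UMIs (quiescent), 41331963 and 37522002 (day 1) and 24108240 and 23677903 (day 6). Cells with at least 200 genes, at least 500 UMIs and under 10% mitochondrial UMIs were kept. The mitochondrial limit was exceeded by 14.1%, 23.9% and 23.6% of quiescent barcodes, 4.11% and 3.80% of day 1 barcodes and 13.3% and 11.4% of day 6 barcodes. Scrublet as implemented in scanpy marked 0.636%, 1.04% and 0.705% of quiescent cells, 1.12% and 2.13% of day 1 cells and 0.0859% and 0.156% of day 6 cells as doublets, and these were removed. At day 6 the caller marked so few of the cells that it cannot be taken to have worked there, so a fixed limit of 0.25 on the doublet score, which removed 193 more cells, was added as an alternative. The kept cells numbered 1563, 1049 and 1971 (quiescent), 8506 and 9437 (day 1) and 3489 and 3201 (day 6), 29216 in all, with median counts of 8039, 8383, 6460, 4225, 3382, 6139 and 6639 UMIs. Pairs of libraries shared at most 0.353% of the barcodes of the smaller one.

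All kept cells were clustered together without batch integration: counts scaled to 10000 per cell and log-transformed, 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1 (seed 1), which gave 28 clusters. A cluster was named "X-like" from 23 fixed marker lists when at least 1 marker of X was among its top 10 genes by fold within libraries (genes of at least 50 CPM, UMIs scaled to a common library total) and at least 3 markers were raised by a log2 fold of 1 at 20 CPM or more. Clusters with equal support for different types, or with too few markers, stayed unnamed. The marker lists were fixed before the data were examined, but this scoring rule was not. Classical-monocyte-like and infiltrating-macrophage-like clusters were combined for tests, as fixed beforehand. Because the genes that name these clusters differ between groups, the cells were also clustered without all fixed markers and without the top 10 genes of every cluster (317 genes, which left 1730 variable genes), and clusters were then named by the same rule; this gave 25 clusters and the same class for 83.5% of cells. As another alternative each cell was put in the class of its highest marker score, standardised within a gate. That score was first standardised per library, and this was changed after class counts had been seen. It placed 59.5% of cells in the class given by clusters, and 11.2% of cells had a gap under 0.1 between their best scores.

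UMIs were summed per library and class (at least 20 cells) and tested with edgeR 4.0.16: filterByExpr, TMM normalization, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Day 6 and quiescent libraries were fitted on their own. Comparisons with day 1 were fitted on all 7 libraries, which share 1 estimate of the spread. CPM values in the text are TMM-scaled within the fit, given as mean ± SD over libraries, and log2 fold changes carry their standard errors. Shares of cells per class were tested with edgeR on cell numbers, for classes with at least 50 cells, with an exact permutation test beside it. The difference between classes in the day 6 change was tested with limma 3.58.1 on the difference of log2 CPM (prior count 2) within libraries. Antibody counts were tested with edgeR with the library as block, scaled by TMM over antibodies. In all, 13 comparisons of genes were made.

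A set of 26 gene lists was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The lists cover the interferon response, NF-kB inflammatory genes, alternative activation, complement and efferocytosis, MHC class I and class II presentation, lipid-associated macrophage genes, matrix, growth factors, glycolysis and hypoxia, oxidative phosphorylation, heme and iron, the lysosome, chemokine receptors and homing, immediate early and dissociation genes, proliferation, resident macrophage identity and infiltrating monocyte and macrophage genes. They also cover transcripts of neutrophils, kidney tubule, injured tubule, endothelium, fibroblasts, lymphocytes and erythroid cells and sex-linked genes. Counts of called genes per list are given over all genes tested and adjusted over the list alone.

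The named genes of each macrophage comparison are the 8 called genes with the largest rise and the 8 with the largest fall, among those with at least 50 CPM in the higher group and groups that do not overlap, up to 4 called members of each called list, and 12 genes named whatever their result (Ccr2, Cx3cr1, Itgam, Itgax, Adgre1, Ly6c2, Arg1, Spp1, Mrc1, Cd81, C1qa and Mki67). Groups, tests, gene lists, this rule and most alternatives were fixed before the data were examined. Some items that the rule takes are not reported here. Other genes are named only where the text says that they were chosen after their values were seen. Gene positions are those of the RefSeq annotation of GRCm38.p6, matched by symbol, which gave a span for 24949 of 30406 genes (82.1%).

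The tests were tried on simulated data with 200 changed genes per comparison. At a simulated log2 fold change of 2, edgeR recovered 85.4% to 100% of changed genes over the 13 comparisons, and at 1 it recovered 46.9% to 92.9%, with 2.23% to 7.09% false among its calls. The limma test of the difference between classes recovered 41.4% at 2 and 1.01% at 1, so it misses most differences of that size. The antibody test recovered 20 of 20 changed antibodies with 1 false call.

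Alternatives changed 1 choice at a time: DESeq2 1.42.0, its size factors in edgeR, no filter or a filter of 10 CPM in 2 libraries, counts thinned to the smallest total, stricter cells (500 genes, 1000 UMIs, 5% mitochondrial), doublets kept, coarser and finer clusters (resolutions 0.5 and 2), score classes, other libraries in the fit, other scalings of antibodies, and each library left out in turn. Single clusters of the resident-macrophage-like, infiltrating and cDC2-like classes, clusters made without the naming genes, all cells with cluster 19 left out, the doublet score limit and a correction for gene span were added after the data had been seen. Score classes were run with both standardisations, per library, which came first, and per gate, which was chosen after class counts had been seen. Where leaving out a library left 1 library in a group, the lone library was assumed to vary like the other group. With 3 against 2 libraries the smallest exact permutation p is 0.2. Each library has its own batch label, so 7 batches and 7 libraries. The titles call quiescent and day 6 samples mice by number, and for day 1 nothing says that the libraries came from separate animals, so p-values there measure the spread between these libraries. UMI sums limit precision: intervals and floors (3 counts over a group) cover counting error only.

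Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.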

Results

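Cells of mouse kidney were profiled by droplet single-cell RNA sequencing in 7 libraries. CD11b+ cells (CD11b is an integrin of myeloid cells) came from 3 quiescent mice and from 2 mice at day 6 after BIRI, an injury treatment whose abbreviation the labels do not spell out. CD45+ cells (CD45 is carried by leukocytes of all kinds) came from 2 libraries at day 1 after BIRI, and 102 surface antibodies were counted in the same cells. The series deals with macrophages and dendritic cells that enter the kidney after acute injury, so the comparisons asked how these cells differed from those of quiescent kidney. The libraries held 13137379, 9845074 and 13813997 UMIs (quiescent), 41331963 and 37522002 (day 1) and 24108240 and 23677903 (day 6), and 29216 cells were kept. Each of the 7 libraries had its own batch label, so batch and group cannot be told apart, and p-values measure the spread between these samples. Day 1 differs from the other groups in gate, assay, batch and gene annotation as well as in time, and every value that sets day 1 against another group carries all of these.

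The 28 clusters gave classes named by fixed markers. Among CD11b+ cells these were resident-macrophage-like, infiltrating-macrophage-like, classical-monocyte-like, nonclassical-monocyte-like, conventional dendritic cell (cDC1-like and cDC2-like), mature-dendritic-cell-like and cycling-like cells, with few neutrophil-like cells. Different clusters held the same class in different groups. Resident-macrophage-like cells lay in cluster 11 in the quiescent (945 cells) and day 6 (263 cells) groups and in cluster 4 at day 1 (1872 cells). Cluster 4 also held 38 day 6 cells (12.6% of the class there) and 7 quiescent ones (0.735%), so the make-up of the class differs between these groups. Values are therefore also given within cluster 11 alone, an alternative chosen after the data had been seen. Infiltrating-macrophage-like cells lay in cluster 2 at day 6 (2449 cells, beside 56 quiescent cells) and in cluster 3 at day 1 (1934 cells). The genes that lead or name the infiltrating-macrophage-like clusters include Arg1, Spp1, Fn1, Thbs1, Ecm1, Cxcl2, Pf4 and Clec4n, so values of these genes in that class are not independent of how the class was made. For this reason values are also given from clusters made without the naming genes, an alternative chosen after the data had been seen. Those clusters were still named from the same markers, so values of these genes there are not fully independent of the class either.

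Infiltrating-macrophage-like cells were the class that rose most among CD11b+ cells at day 6, and resident-macrophage-like cells made up a smaller share. Shares are parts of a whole, so the rise of this class by itself lowers the shares of all others. A lower share is therefore not by itself a loss of cells. With clusters made without the naming genes, infiltrating-macrophage-like cells were 0.256%, 0.0953% and 0.355% of quiescent cells and 30.9% and 36.1% of day 6 cells (log2 ratio 7.01, edgeR adjusted p = 1e-05). With all genes they were 1.10% ± 0.712 (SD, n = 3) and 36.8% ± 3.55 (SD, n = 2), a log2 ratio of 4.99 ± 0.58 (SE, edgeR, adjusted p = 0.00023). Resident-macrophage-like cells, the long-lived macrophages of the tissue, were 23.1%, 26.2% and 20.2% of quiescent cells and 9.14% and 9.81% of day 6 cells in the clusters without the naming genes (log2 ratio -1.29, edgeR adjusted p = 0.00667). In the clusters of all genes they were 21.4% ± 3.32 and 4.52% ± 0.550 (log2 ratio -2.24 ± 0.38, edgeR adjusted p = 0.00177). The fall was smaller and not called when cells were classed by a marker score standardised per gate, a standardisation chosen after class counts had been seen (log2 ratio -0.39, edgeR adjusted p = 0.499). It was also not called without day 6 library 2 (-2.13, edgeR adjusted p = 0.201) or 3 (-2.37, edgeR adjusted p = 0.127). Mature-dendritic-cell-like cells, which carry genes of migrating dendritic cells, rose from 0.636% ± 0.108 to 1.81% ± 0.0379 (log2 ratio 1.48, edgeR adjusted p = 0.0143). With the score standardised per library, the version made first, the log2 ratio was 0.42 for mature-dendritic-cell-like cells (edgeR adjusted p = 0.747, not called), 2.80 for infiltrating-macrophage-like cells (called) and -0.14 for resident-macrophage-like cells (edgeR adjusted p = 0.770, not called). Cells in unnamed clusters fell from 3.91% ± 0.860 to 1.20% ± 0.242 (log2 ratio -1.70, edgeR adjusted p = 0.0113), and 169 of the 182 quiescent and 64 of the 80 day 6 ones lay in cluster 19, which is led by the interferon-induced genes Cxcl9, Cxcl10, Rsad2 and Ifit3. The calls of mature-dendritic-cell-like and unnamed cells were also lost without either day 6 library, and without library 2 or 3 only 1 of the 11 classes was called, against 4 with all libraries and 7 without quiescent library 1. cDC2-like cells were 40.9% ± 10.2 and 21.5% ± 0.190 (log2 ratio -0.93, edgeR adjusted p = 0.0692), and were called lower with the clusters made without the naming genes (-0.98, edgeR adjusted p = 0.0388). Classical-monocyte-like (13.3% and 20.6%, edgeR adjusted p = 0.287), nonclassical-monocyte-like (log2 ratio -0.39, adjusted p = 0.422), cDC1-like (0.04, adjusted p = 0.936), cycling-like (-0.64, adjusted p = 0.270), neutrophil-like (-0.22, adjusted p = 0.887) and proximal-tubule-like cells (-1.52, adjusted p = 0.0666) were not called. With 3 against 2 libraries the smallest two-sided exact permutation p is 0.2, and no share reaches 0.05 by that test.

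**Figure D1:**
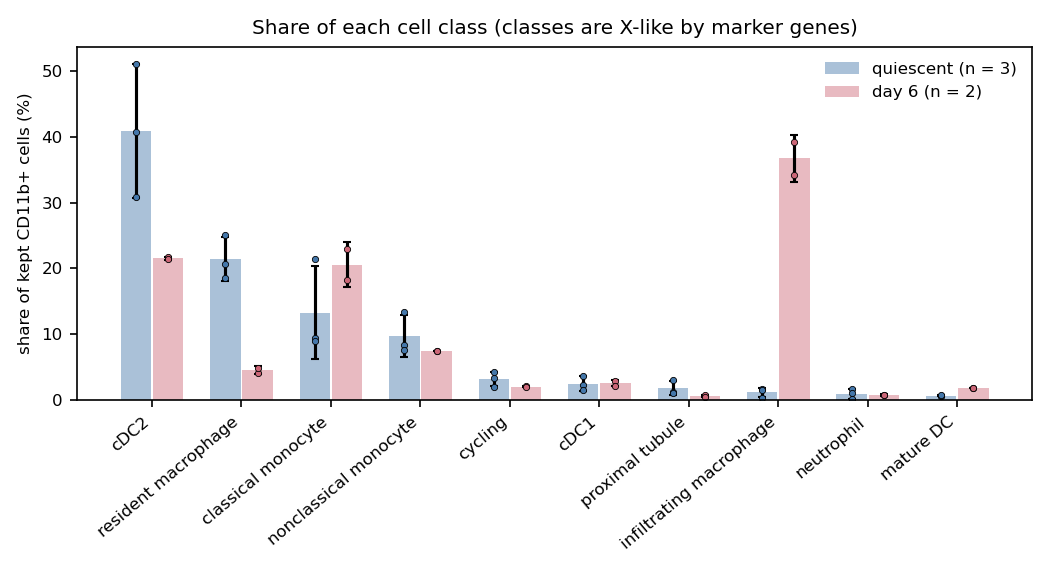
Share of kept CD11b+ cells (%, linear axis) in each named class, for quiescent (n = 3) and day 6 (n = 2) libraries, with points for libraries, bars for means and error bars for the SD. Infiltrating-macrophage-like cells sit at 34.2% and 39.3% at day 6 and at or below 1.60% in quiescent libraries.

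Resident-macrophage-like cells carried more transcripts of lipid handling and matrix genes at day 6 and fewer of MHC class I genes. camera called these lists over the class with an estimated correlation too (adjusted p = 0.0342, 0.0373 and 0.0373), and within cluster 11 alone at the preset correlation but not with an estimated one (adjusted p = 0.0791, 0.0742 and 0.0791). Arg1, the enzyme that turns arginine into ornithine, was read in 2 quiescent and 108 day 6 counts of the class, a ratio of 213 (95% counting interval 59.0 to 1760.0), with 76.6 ± 33.0 CPM at day 6 (SD, n = 2) and 0.360 ± 0.312 CPM in quiescent cells (SD, n = 3). Of these 108 counts 103 lay in the 38 cells of cluster 4 (1217 and 526 CPM in day 6 libraries 2 and 3). The 263 day 6 cells of cluster 11 held 5 (3.30 and 4.57 CPM), and the gene was not tested there. Fn1, the matrix protein fibronectin, rose by a log2 fold of 4.29 ± 0.28 (SE, edgeR, adjusted p = 1.4e-06), from 7.66 ± 4.25 to 149 ± 26.0 CPM. Spp1, the secreted glycoprotein osteopontin, rose by 3.35 ± 0.26 (edgeR, adjusted p = 4.2e-06), and Fabp5, a fatty acid binding protein, by 3.32 ± 0.25 (adjusted p = 4.2e-06). AA467197 (2.97), Gda (guanine deaminase, 2.70), Clec4n (dectin-2, 2.13) and Trem2 (a lipid-sensing receptor, 1.95 ± 0.17, adjusted p = 1.6e-05) rose as well. Within cluster 11 the log2 fold was 3.85 for Fn1, 1.85 for Spp1, 1.58 for Fabp5 and 1.70 for Trem2, all called by edgeR. The largest falls were those of Mmp13 (collagenase 3, -4.89 ± 0.43), H2-Q6 (3 counts at day 6, ratio 23.3, interval 7.97 to 113), Ccl5 (a chemokine, -3.53), Cd209a (-3.32), H2-Oa (-3.22), H2-Q7 (-3.13 ± 0.26), Kap (-2.64) and Cadm1 (-2.61). H2-Q6 and H2-Q7 are near-identical MHC class I genes whose reads can be split between them, so each value is uncertain. Cd209a and Cadm1 are markers of dendritic cells, and Kap is a transcript of proximal tubule. Each named gene was on the same side in both day 6 libraries against all 3 quiescent ones. The rule for the largest rises and falls requires this, so it gives them no further support. On GRCm38, Arg1 (ENSMUSG00000019987) lies on chromosome 10 at 24915207 to 24927470, Spp1 (ENSMUSG00000029304) on chromosome 5 at 104435111 to 104441053, Fn1 (ENSMUSG00000026193) on chromosome 1 at 71585473 to 71653280, Fabp5 (ENSMUSG00000027533) on chromosome 3 at 10012585 to 10016610, Trem2 (ENSMUSG00000023992) on chromosome 17 at 48346401 to 48352276 and H2-Q7 (ENSMUSG00000060550) on chromosome 17 at 35439140 to 35443773.

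By fixed lists, 9 of 13 lipid-associated macrophage genes rose and none fell (10 and 1 adjusted over the list alone, camera adjusted p = 1.2e-23, and 0.0342 with an estimated correlation, the re-estimated adjusted p). Fabp5, Trem2 and Ctsl (1.49), a lysosomal protease, were among them. Of 8 matrix genes 5 rose (6 adjusted over the list alone, camera adjusted p = 1.6e-19, re-estimated adjusted p = 0.0373), including Thbs1 (3.15), Ecm1 (2.39) and Tgfbi (0.98), a protein induced by TGF-beta. Of 10 infiltrating monocyte and macrophage genes 4 rose (6 adjusted over the list alone, camera adjusted p = 1.9e-18, re-estimated adjusted p = 0.0373). Of 7 alternative activation genes 2 rose (4 adjusted over the list alone, camera adjusted p = 1.2e-08, re-estimated adjusted p = 0.0373), which were Arg1, mostly in cluster 4, and Mrc1, the mannose receptor, at 0.97. Of 9 MHC class I genes 4 fell (7 adjusted over the list alone, camera adjusted p = 1.4e-08, re-estimated adjusted p = 0.0373), including H2-K1 (-0.87) and B2m (-0.48). The matrix and infiltrating lists share Fn1, Thbs1 and Ecm1 and are not independent. The 5 lists above were called with an estimated correlation over the class, and the following were not. Of 16 interferon response genes 3 fell (9 adjusted over the list alone, camera adjusted p = 1.2e-08, re-estimated adjusted p = 0.0818), including Ifit2 (-1.84) and Ifit3 (-1.22). Of 17 immediate early genes, a list that also marks stress of tissue dissociation, 11 fell (14 fell and 1 rose adjusted over the list alone, camera adjusted p = 5.7e-15, re-estimated adjusted p = 0.0636), including Jund (-1.13), Ier2 (-1.04) and Jun (-0.70). Of 13 NF-kB inflammatory genes 5 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 6.5e-06, re-estimated adjusted p = 0.163), and Ccl3 (-1.62), Ccl4 (-1.80) and Il1b (-1.0) were among those that fell. Of 9 MHC class II genes 3 fell (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0031, re-estimated adjusted p = 0.231), with Cd74 at -0.50 and H2-Eb1 at -0.48. Of 13 lysosome genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.00022, re-estimated adjusted p = 0.269), Ctsd by 1.74. Of 14 oxidative phosphorylation genes 2 rose (5 adjusted over the list alone, camera adjusted p = 0.00096, re-estimated adjusted p = 0.269). Of 14 glycolysis and hypoxia genes 1 rose (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.011, re-estimated adjusted p = 0.192), which was Ldha (0.69). Camera called none of the other lists. Complement and efferocytosis had 0 of 13 genes called (C1qa at 0.07, adjusted p = 0.0958), and heme and iron 2 of 9 higher (adjusted p = 0.076). Growth factors (1 higher and 1 lower of 8, adjusted p = 0.548), chemokine receptors and homing (1 and 1 of 10, median -0.04, mean 0.02, adjusted p = 0.543) and proliferation (0 of 10, median 0.09, mean -0.01, adjusted p = 0.878) showed no common direction. Resident macrophage identity had 2 of 12 genes lower (Cd81 and Itga9, median 0.09, mean -0.15, adjusted p = 0.543). Transcripts of kidney tubule (1 higher and 1 lower of 10, adjusted p = 0.35), injured tubule (1 of 3 higher, median -0.33, mean 0.64, adjusted p = 0.35) and sex-linked genes (0 of 4, adjusted p = 0.814) were not called as lists. The neutrophil, endothelium, fibroblast, lymphocyte and erythroid lists had too few tested genes in this class. Within cluster 11 alone camera called 11 lists, against 12 over the class, and 0 with an estimated correlation (lowest adjusted p = 0.0742, and 7 lists at an unadjusted p under 0.05). There 4 of 12 lipid-associated genes rose and 2 fell (7 and 2 adjusted over the list alone, median 0.64, camera adjusted p = 2.1e-06, re-estimated adjusted p = 0.0791), and Ctsl (0.90, edgeR adjusted p = 0.0529), Ctsd (0.60, adjusted p = 0.143) and Ldha (0.55, adjusted p = 0.0826) were not called. The lysosome (camera adjusted p = 0.0875) and glycolysis and hypoxia lists (adjusted p = 0.243) were not called there, and kidney tubule transcripts were (1 rose and 1 fell of 10, 1 and 2 adjusted over the list alone, median -0.84, camera adjusted p = 0.018, re-estimated adjusted p = 0.432).

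In all, edgeR called 300 of 8674 genes in resident-macrophage-like cells at day 6, 163 higher and 137 lower, with 661033 to 1941018 UMIs per library. The count is sensitive to libraries and to the class border: it was 97 without quiescent library 2, 578 without quiescent library 3, 59 without day 6 library 2, 50 without day 6 library 3, 240 within cluster 11 alone (108 higher, 132 lower, with 221 of the 300 among them), 584 with clusters made without the naming genes (228 of the 300 among them) and 2660 with classes by marker score. In the clusters made without the naming genes Arg1 stood at a log2 fold of 6.53 (47.5 and 25.9 CPM at day 6), Fn1 at 3.45, Spp1 at 2.72, Fabp5 at 2.82 and Trem2 at 1.64, all called. With doublets kept, the day 6 resident-macrophage-like cells held 15 Arg1 counts (4.81 and 4.93 CPM) and the gene was not tested, while Spp1 (2.15) and Fn1 (1.76) were still called, and with coarser clusters Fn1 stood at 2.03. With finer clusters Arg1 stood at 6.70 and 11.5 CPM (log2 fold 4.48) and Spp1 at a log2 fold of 2.12. Classes by marker score moved these genes the other way. Standardised per gate, the log2 fold was 9.87 for Arg1, 6.695 for Fn1 and 4.32 for Spp1, and standardised per library 12.75, 7.44 and 4.58. Il1b turned from -1.0 to 1.13 with the clusters made without the naming genes, to 1.12 with doublets kept, to 1.26 with finer clusters and to 1.94 with classes by marker score. With the clusters made without the naming genes Ier2 and Egr1 turned to 0.24 and 0.35, and Jun (-0.34, edgeR adjusted p = 0.143) and Ccl4 (-0.78, edgeR adjusted p = 0.0541) were not called, so the falls of Il1b, Ier2, Egr1, Jun and Ccl4 depend on the class border. Ccl3 stayed called there, at -0.95.

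Classical-monocyte-like and infiltrating-macrophage-like cells were tested together as the infiltrating class, as fixed beforehand. This class consisted mainly of monocyte-like cells in quiescent kidney (56 of 666 cells in the macrophage-like clusters) and mainly of macrophage-like cells at day 6 (2452 of 3835), so its day 6 change is in large part a difference between these classes. At day 6 it carried more transcripts of inflammatory cytokines, growth factors, complement and lipid handling and fewer of interferon response and MHC class I genes, by lists that camera called at the preset correlation and did not call with an estimated one (adjusted p = 0.0612 to 0.282). Spp1 stood at a log2 fold of 6.94 ± 0.37 (SE, edgeR, adjusted p = 0.00034), and Arg1, at 0 counts in quiescent cells, was at least 930-fold higher (floor of 3 counts over the group, 495 ± 198 CPM at day 6). Cxcl14, a chemokine, was read in 3 quiescent counts (ratio 105, interval 36.0 to 510.0). Vegfa, the endothelial growth factor, rose from 2.47 ± 2.78 to 90.7 ± 10.1 CPM (4.66 ± 0.39, edgeR adjusted p = 0.00065). Socs2 (a suppressor of cytokine signalling, 5.23), Pf4 (platelet factor 4, 5.17), Ccl24 (5.11) and Cxcl1 (4.74), chemokines, were among the 8 largest rises. Cd177, a neutrophil surface protein, fell from 101 ± 11.4 to 14.5 ± 1.56 CPM (-2.84 ± 0.15, edgeR adjusted p = 0.00034). Ly6c2, a marker of classical monocytes, fell from 912 ± 343 to 140.03 ± 26.7 CPM (-2.75 ± 0.33, adjusted p = 0.0021). F13a1 (coagulation factor XIII, -2.14), C3 (complement component, -2.10), Ifi211 (interferon-activated, -2.02), Gm1673 (-1.97) and the tubule transcript Kap (-1.96) also fell. Clusters made without the naming genes gave Spp1 7.17, Pf4 9.28, Vegfa 4.53, Cd177 -2.99 and Ly6c2 -2.83, all called. On GRCm38, Vegfa (ENSMUSG00000023951) lies on chromosome 17 at 46016993 to 46032377, Cxcl14 (ENSMUSG00000021508) on chromosome 13 at 56288643 to 56296811, Pf4 (ENSMUSG00000029373) on chromosome 5 at 90772435 to 90773383 and Cd177 (ENSMUSG00000052212) on chromosome 7 at 24743983 to 24760334.

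By fixed lists, 14 of 16 interferon response genes fell in this class (14 adjusted over the list alone, camera adjusted p = 9.9e-20, re-estimated adjusted p = 0.0612), among them Irf7 (-1.87 ± 0.14), a transcription factor of the response, and Rtp4 (-1.65). Of 9 MHC class I genes 8 fell (9 adjusted over the list alone, camera adjusted p = 9.2e-07, re-estimated adjusted p = 0.282), including H2-D1 (-0.86) and the peptide transporter Tap1 (-1.09). Of 17 NF-kB inflammatory genes 11 rose (13 adjusted over the list alone, camera adjusted p = 7.2e-12, re-estimated adjusted p = 0.0612). Il1b, the cytokine interleukin-1 beta, rose from 923 ± 198 to 3502 ± 88.4 CPM (1.87 ± 0.16, edgeR adjusted p = 0.00072), with the chemokines Cxcl2 (2.89) and Cxcl3 (4.16). Of 12 growth factors 8 rose (9 adjusted over the list alone, camera adjusted p = 2.5e-10, re-estimated adjusted p = 0.0954), including Hbegf (3.24), Pdgfa (4.50) and Igf1 (2.53). Of 14 lipid-associated genes 9 rose (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 2e-14, re-estimated adjusted p = 0.0612), including Gpnmb (4.72), Fabp5 (2.41) and Trem2 (1.81). Of 13 complement and efferocytosis genes 8 rose (9 adjusted over the list alone, camera adjusted p = 4.7e-09, re-estimated adjusted p = 0.18), including the receptors C3ar1 (3.50) and Mertk (3.17). Of 8 alternative activation genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 1.4e-09, re-estimated adjusted p = 0.0612), with Mrc1 at 2.79 and Tgm2 at 2.68. Matrix genes rose in 5 of 13 and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 3.2e-05, re-estimated adjusted p = 0.18), with Timp1 at 4.01. Glycolysis and hypoxia genes rose in 8 of 15 (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 6.6e-05, re-estimated adjusted p = 0.201), with Ldha at 1.19. Immediate early genes rose in 8 of 17 and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 1.9e-05, re-estimated adjusted p = 0.299), with Fosb at 2.23. Resident macrophage identity genes rose in 5 of 12 (5 adjusted over the list alone, camera adjusted p = 0.00053, re-estimated adjusted p = 0.303), with the complement chains C1qa (3.37) and C1qb (3.24). MHC class II genes rose in 3 of 9 (4 adjusted over the list alone, camera adjusted p = 0.0092, re-estimated adjusted p = 0.413), with H2-DMb1 at 0.68. Heme and iron genes rose in 3 of 9 (4 adjusted over the list alone, camera adjusted p = 0.015, re-estimated adjusted p = 0.201), with Fth1 at 1.26. Proliferation genes rose in 3 of 11 and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.015, re-estimated adjusted p = 0.263), with Mcm3 at 1.14. Injured tubule genes rose in 2 of 3 (2 adjusted over the list alone, camera adjusted p = 0.0033, re-estimated adjusted p = 0.18), namely Cdkn1a (1.31) and Clu (2.98). Transcripts of neutrophils fell beside these groups in 2 of 4 (2 adjusted over the list alone, camera adjusted p = 0.041, re-estimated adjusted p = 0.349), Csf3r at -1.32 and Hdc at -1.64. None of the 16 called lists was called with an estimated correlation. Infiltrating monocyte and macrophage genes (2 higher and 5 lower of 11, median -1.05, mean 0.64, adjusted p = 0.661), lysosome (4 and 1 of 13, adjusted p = 0.077) and oxidative phosphorylation (1 and 1 of 14, adjusted p = 0.994) were not called as lists. Chemokine receptors and homing (2 and 4 of 11, adjusted p = 0.308), kidney tubule (2 and 2 of 11, median -0.14, mean 0.34, adjusted p = 0.494) and sex-linked genes (0 of 4, adjusted p = 0.994) were not called either. Ccr2 (-0.25, edgeR adjusted p = 0.49), Cx3cr1 (-0.43), Itgam (0.20), Adgre1 (-0.17) and Mki67 (0.66) were not called.

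**Figure D2:**
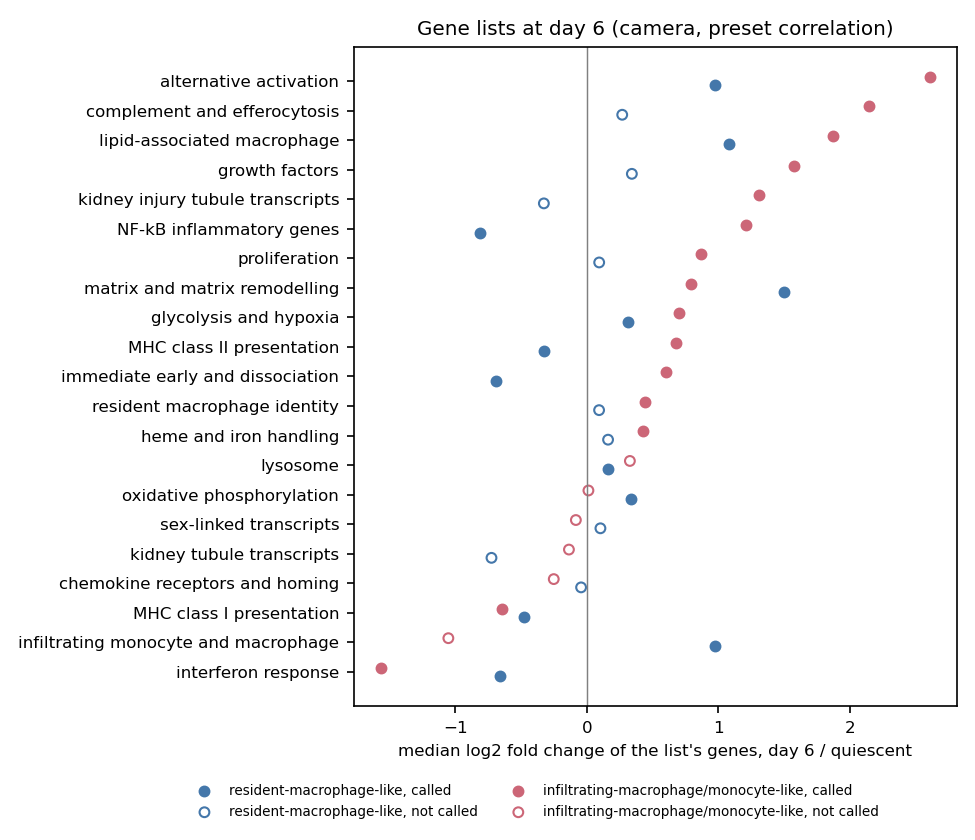
Median log2 fold change (day 6 against quiescent) of the genes of each fixed list, in resident-macrophage-like and infiltrating cells, with filled points for lists called by camera at the preset correlation. Lipid-associated genes stand at 1.08 and 1.87 and interferon response genes at -0.66 and -1.56 in these classes.

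In this class edgeR called 1497 of 9479 genes, 757 higher and 740 lower. The count was 877 without quiescent library 2, 2405 without quiescent library 3, 387 without day 6 library 2 and 263 without day 6 library 3. Within single classes fewer genes were called. In classical-monocyte-like clusters alone edgeR called 36 genes (21 higher, 15 lower), among them Il1b (1.18, adjusted p = 0.027), Spp1 (2.94), Fosb (1.40), Irf7 (-0.78, adjusted p = 0.049) and Cd177 (-1.66), while Vegfa (0.79), Mrc1 (0.11), C1qa (1.11), H2-D1 (-0.48), Rtp4 (-0.83), Ifi211 (-1.16) and Ly6c2 (-1.37) were not called. In infiltrating-macrophage-like clusters alone, where quiescent library 2 had only 3 cells and did not enter, it called 477 genes. There Arg1, Spp1 (4.66), Vegfa (5.80), Fabp5 (3.98), Trem2 (1.84) and Il1b (0.71) were called higher and Irf7 (-2.72), Tap1 (-2.0) and H2-D1 (-0.92) lower, C1qa (0.30) and Mertk (1.26) were not called, and H2-DMb1 (-0.79) and Cd81 (-0.95) were called lower, against their direction in the combined class. The growth factors Hbegf (1.70, edgeR adjusted p = 0.166), Pdgfa (1.88, adjusted p = 0.131) and Igf1 (-0.65, adjusted p = 0.629), the chemokines Cxcl1 (1.52, adjusted p = 0.0872) and Cxcl3 (3.01, adjusted p = 0.130) and Timp1 (1.59, adjusted p = 0.203) were not called there either. Cd177 (7.5), F13a1 (0.79) and Gm1673 (0.18), which fell in the combined class, turned sign there and were not called.

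The difference between the resident-macrophage-like and infiltrating changes was then tested gene by gene. Some inflammatory genes lay on opposite sides: Il1b at -1.0 and 1.87 in resident-macrophage-like and infiltrating cells, the chemokines Ccl3 (-1.62 and 1.26) and Ccl4 (-1.80 and 1.38), the early transcription factor Egr1 (-0.89 and 1.75) and the tetraspanin Cd81 (-1.03 and 1.89). The resident-macrophage-like falls of Il1b, Egr1 and Ccl4 depend on the class border and that of Ccl3 was smaller with another border, as given above, and none of these differences passed the test itself (Il1b 2.87, limma adjusted p = 0.107, with 0.115 for Ccl3, 0.148 for Ccl4, 0.115 for Egr1 and 0.238 for Cd81). In all, limma called 0 of 9139 differences, against 1634 at an unadjusted p under 0.05. It called 17 (14 and 3 by direction) under a filter of 10 CPM, with adjusted p from 0.0430 to 0.0492, among them Flt1 (-2.74). Of 8488 genes tested in both classes 126 were called in both, 100 with the same sign and 26 with opposite signs, and the comparisons use the same libraries, so this overlap is not a measure of a shared change.

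With all macrophage and monocyte classes combined, and in all CD11b+ cells, the values mix changes within classes with the shift of shares above. In the combined macrophages and monocytes Arg1 was read in 2 quiescent counts against 12781 at day 6 (ratio 2920, interval 809 to 24100). Spp1 rose by 6.21, Vegfa by 5.59 and Fabp5 by 2.88, and Cd209a (-3.38) and H2-Q7 (-2.91) fell. Here 15 of 17 interferon response genes fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 1.5e-18, re-estimated adjusted p = 0.0748). All 9 MHC class I genes fell (9 adjusted over the list alone, camera adjusted p = 6.1e-09, re-estimated adjusted p = 0.218). Of 15 glycolysis and hypoxia genes 13 rose (14 adjusted over the list alone, camera adjusted p = 9.5e-08, re-estimated adjusted p = 0.218). Of 14 lipid-associated genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 7e-17, re-estimated adjusted p = 0.0535). Of 4 fibroblast transcripts 2 rose beside them (3 adjusted over the list alone, camera adjusted p = 0.011, re-estimated adjusted p = 0.215), the collagens Col3a1 (2.58) and Col1a2 (2.36). The infiltrating monocyte and macrophage list tested higher (4 rose and 2 fell of 11, 4 and 3 adjusted over the list alone, camera adjusted p = 0.026, re-estimated adjusted p = 0.487) with a median of -0.12 and a mean of 1.19. edgeR called 2470 of 10477 genes (1253 higher, 1217 lower), 1378 without quiescent library 2, 622 without day 6 library 2 and 478 without day 6 library 3. In all CD11b+ cells Arg1 (10.60), Spp1 (5.29), Cxcl2 (3.84) and Ccl17 (3.57) rose and Cxcl9 (-2.84), H2-Oa (-2.13) and Ly6a (-2.11) fell. Transcripts of other cells moved with them. Of 13 kidney tubule genes 6 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.016, re-estimated adjusted p = 0.582). Of 7 endothelium genes 2 fell (2 adjusted over the list alone, camera adjusted p = 0.02, re-estimated adjusted p = 0.467), Flt1 by -2.14 and Kdr by -1.72. Of 5 fibroblast genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.024, re-estimated adjusted p = 0.374), with Col1a1 at 3.04. Of 7 injured tubule genes 4 rose (4 adjusted over the list alone, camera adjusted p = 0.00027, re-estimated adjusted p = 0.25), with Havcr1, kidney injury molecule 1, at 0 quiescent counts and at least 17.6-fold higher. Lymphocyte (0 of 8, camera adjusted p = 0.42), neutrophil (0 of 8, adjusted p = 0.52) and sex-linked genes (0 of 4, adjusted p = 0.81) were not called, and the erythroid list had too few tested genes in all comparisons. edgeR called 2831 of 11849 genes (1481 higher, 1350 lower), 4412 without quiescent library 1, 1097 without quiescent library 2 and 246 and 201 without day 6 libraries 2 and 3.

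At day 1 the CD45+ gate also let in lymphocytes and neutrophils, so shares are given per library and are not compared with the CD11b+ groups. Neutrophil-like cells were 20.9% (exact 95% interval 20.1 to 21.8) and 9.61% (9.02 to 10.2) of cells in libraries 1 and 2. Classical-monocyte-like cells were 20.6% (19.7 to 21.4) and 15.2% (14.5 to 15.9), infiltrating-macrophage-like cells 13.3% (12.5 to 14) and 8.66% (8.10 to 9.24), and resident-macrophage-like cells 6.28% (5.77 to 6.81) and 14.2% (13.5 to 15). T-cell-like cells were 5.54% and 9.0%, B-cell-like cells 2.99% and 5.28%, NK-cell-like cells 0.929% and 1.79%, cDC1-like cells 0.459% and 0.964% and cDC2-like cells 0.494% and 0.996%. Cells in unnamed clusters were 20.2% (19.3 to 21) and 23.3% (22.5 to 24.2), the largest of these shares in library 2. The libraries differed from each other by more than the counting interval in each of these classes. With clusters made without the naming genes unnamed cells were 5.56% and 7.26%, and the classical-monocyte-like share was 29.6% and 21.9%, the resident-macrophage-like share 7.42% and 17.6% and the infiltrating-macrophage-like share 16.5% and 10.8%, so the shares depend on how clusters were made.

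Resident-macrophage-like cells of day 1 carried far less MHC class II and interferon response transcript than those of quiescent kidney and more of heme and iron genes, with gate, assay, batch and annotation differing too. These lists were not called with an estimated correlation. H2-Eb1, an MHC class II chain, stood at 2349 ± 182 CPM at day 1 and 18242 ± 747 CPM in quiescent cells (-3.02 ± 0.10, edgeR adjusted p = 1.3e-13). All 9 MHC class II genes fell (9 adjusted over the list alone, camera adjusted p = 7.1e-18, re-estimated adjusted p = 0.0724). Hmox1, the enzyme that breaks down heme, stood at 1584 ± 169 and 53.1 ± 25.8 CPM (4.84 ± 0.36, edgeR adjusted p = 3.2e-09). With Slc40a1 (the iron exporter ferroportin, 5.82) and Fth1 (ferritin heavy chain, 1.59) it was among 11 of 12 heme and iron genes that rose (11 adjusted over the list alone, camera adjusted p = 4.6e-07, re-estimated adjusted p = 0.145). Of 16 interferon response genes 15 fell (15 adjusted over the list alone, camera adjusted p = 9.4e-12, re-estimated adjusted p = 0.145), with Irf7 at -3.40 and Ifit3 at -3.98. Of 9 MHC class I genes 8 fell (8 adjusted over the list alone, camera adjusted p = 6.9e-05, re-estimated adjusted p = 0.145). NF-kB inflammatory genes rose in 13 of 16 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.0023, re-estimated adjusted p = 0.25), with Cxcl2 at 3.68 and Tnf at 1.15. Matrix genes rose in 9 of 10 (9 adjusted over the list alone, camera adjusted p = 4.3e-05, re-estimated adjusted p = 0.155). Lipid-associated genes rose in 7 of 13 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.018, re-estimated adjusted p = 0.178), with Cd63 at 3.65. Complement genes rose in 11 of 13 and fell in 1 (11 and 2 adjusted over the list alone, camera adjusted p = 0.017, re-estimated adjusted p = 0.572), with C5ar1 at 3.19. Neutrophil transcripts rose beside these groups in 5 of 6 (5 adjusted over the list alone, camera adjusted p = 0.013, re-estimated adjusted p = 0.33). S100a9 was read in 1 quiescent count (ratio 480, interval 86.1 to 18900.0) and S100a8 rose by 5.67. Kidney tubule transcripts fell in 8 of 10 and rose in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00039, re-estimated adjusted p = 0.25), with Kap at -4.49. Ccr2 (-3.59), Cd209a (-7.07) and Ly6c2 (-4.92) fell, Spp1 (0.64) and Mrc1 (0.73) rose, and Cx3cr1 (0.04, adjusted p = 0.81) and Cd81 (0.28, adjusted p = 0.19) were not called. Long genes stood higher at day 1 than short ones. After a correction for gene span Adgre1, which encodes F4/80, stood at -0.47 in place of 0.46 and Mrc1 at -0.06. Several of the largest changes (Nme2, Rnasek, Timm23, Cmss1, AC160336.1, Rps27rt) belong to genes that were near 0 in all libraries of 1 annotation. Of 9588 genes edgeR called 5370 (2794 higher, 2576 lower), and 4582 after the span correction (2101 higher, 2481 lower), which turns the majority. This correction was added after the data had been seen.

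The infiltrating class of day 1 was set against the quiescent one under the same confounding, again with quiescent cells that were mostly monocyte-like. Arg1 was at 0 in quiescent cells and at least 884-fold higher at day 1 (381 ± 189 CPM). Spp1 stood at 6.67 ± 0.35 (edgeR, adjusted p = 4.3e-07) and Ecm1 at 4.28, and these are genes that name the class (Spp1 at 6.46 with clusters made without the naming genes). The chemokines Cxcl3 (7.86) and Ccl2 (2.72), the receptors C5ar1 (3.86) and Mertk (3.87) and Hmox1 (2.61) rose, and Ly6c2 (-3.23), Cx3cr1 (-1.39) and Ccr2 (-0.98) fell. All 17 interferon response genes fell (17 adjusted over the list alone, camera adjusted p = 1.8e-10, re-estimated adjusted p = 0.314). Of 9 MHC class I genes 8 fell (8 adjusted over the list alone, camera adjusted p = 1.7e-06, re-estimated adjusted p = 0.341), as did 8 of 9 MHC class II genes (9 adjusted over the list alone, camera adjusted p = 0.013, re-estimated adjusted p = 0.498). H2-Eb1 stood at -1.51, but at 0.29 (edgeR adjusted p = 0.28) with clusters made without the naming genes. NF-kB genes rose in 12 of 17 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.0023, re-estimated adjusted p = 0.314). Complement genes rose in 10 of 13 and fell in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.0015, re-estimated adjusted p = 0.397), and matrix genes rose in 9 of 14 (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0014, re-estimated adjusted p = 0.314). Alternative activation (7 higher and 1 lower of 11, camera adjusted p = 0.0047, re-estimated adjusted p = 0.314) and lipid-associated genes (9 higher and 3 lower of 14, camera adjusted p = 0.048, re-estimated adjusted p = 0.44) had the same counts adjusted over the list alone. Glycolysis and hypoxia genes rose in 11 of 15 and fell in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.012, re-estimated adjusted p = 0.43), and heme and iron genes rose in 10 of 12 (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.012, re-estimated adjusted p = 0.341). Neutrophil transcripts rose beside them in 6 of 8 and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.048, re-estimated adjusted p = 0.44). Tubule transcripts fell in 11 of 12 and rose in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0015, re-estimated adjusted p = 0.335). Oxidative phosphorylation genes fell in 7 of 14 (7 adjusted over the list alone, camera adjusted p = 0.018, re-estimated adjusted p = 0.341), with Cox6c at -1.43. Lymphocyte (3 higher and 2 lower of 6, adjusted p = 0.44) and fibroblast genes (1 of 4 lower, adjusted p = 0.466) were not called as lists. edgeR called 5955 of 12151 genes (3528 higher, 2427 lower), and 4973 after the span correction (2328 higher, 2645 lower).

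Between the injured groups, day 6 against day 1, the same confounding applies. Resident-macrophage-like cells of day 6 carried more MHC class II transcript, with 9 of 9 genes higher (9 adjusted over the list alone, camera adjusted p = 3.2e-22, re-estimated adjusted p = 0.0401). H2-Eb1 stood at 12679 ± 438 CPM at day 6 and 2349 ± 182 CPM at day 1 (2.53 ± 0.10, edgeR adjusted p = 3.9e-12). They also carried more Ccr2 (4.2), a chemokine receptor of monocytes, Fabp5 (4.11) and Fn1 (3.18), and less Hmox1 (-3.00), Cxcl2 (-3.07) and Cd36 (a lipid scavenger receptor, -5.03). With the day 6 and quiescent cells of cluster 11 alone Fabp5 stood at 2.38, Fn1 at 2.76 and Hmox1 at -4.88, all called. Arg1 stood at 4.67 over the class, from counts that lay mostly in cluster 4, and was not tested with cluster 11 alone. Heme and iron genes fell in 11 of 12 (12 adjusted over the list alone, camera adjusted p = 4.6e-07, re-estimated adjusted p = 0.206), and NF-kB genes fell in 13 of 16 and rose in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 2.1e-06, re-estimated adjusted p = 0.206). Interferon response genes rose in 12 of 16 (12 adjusted over the list alone, camera adjusted p = 1.5e-05, re-estimated adjusted p = 0.23), and tubule transcripts rose beside them in 7 of 10 (7 adjusted over the list alone, camera adjusted p = 0.0081, re-estimated adjusted p = 0.412). These lists moved opposite to their day 1 direction against quiescent cells, and since both comparisons use the day 1 libraries, part of this follows from those libraries alone. Cxcl2 turned to 0.92 with classes by marker score. The infiltrating class of day 6 also had more MHC class II, with 9 of 9 genes higher (9 adjusted over the list alone, camera adjusted p = 0.00081, re-estimated adjusted p = 0.529) and H2-DMb1 at 2.07. Mmp12 (a macrophage elastase, 4.42), Vegfa (2.14) and Cd81 (2.10) were higher, while Arg1 (0.45), Spp1 (0.31) and Mrc1 (0.21) were not called. Neutrophil transcripts were lower beside them in 7 of 8 (8 adjusted over the list alone, camera adjusted p = 0.013, re-estimated adjusted p = 0.529). Tubule transcripts were higher in 11 of 12 (11 adjusted over the list alone, camera adjusted p = 0.00036, re-estimated adjusted p = 0.529) and fibroblast transcripts in 4 of 4 (4 adjusted over the list alone, camera adjusted p = 0.0087, re-estimated adjusted p = 0.438). edgeR called 4013 of 9588 genes in resident-macrophage-like cells (1887 higher, 2126 lower, and 2668 without day 6 library 3) and 6675 of 12151 in infiltrating cells (3005 higher, 3670 lower). After the span correction it called 3140 (1848 higher, 1292 lower) and 5533 (2959 higher, 2574 lower), so that the majority turned in both.

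Surface antibodies at day 1 separated infiltrating-macrophage-like and classical-monocyte-like cells from resident-macrophage-like cells in the same libraries. CD106 (VCAM-1, -3.27 ± 0.06, edgeR adjusted p = 0.0018), I-A/I-E (MHC class II, -2.84 ± 0.22, adjusted p = 0.0097), CD11c (-2.73), F4/80 (-2.04 ± 0.09, adjusted p = 0.0050) and CD63 (-1.60) were lower on the infiltrating cells. Ly-6C (2.88 ± 0.25, adjusted p = 0.0108), CD61 (2.46), integrin beta 7 (2.36), CD44 (2.21) and CD11b (1.71 ± 0.20, adjusted p = 0.0186) were higher. Itgb3, the gene of CD61, was almost unread (0.621 CPM in infiltrating and 0.381 in resident-macrophage-like cells), so RNA gives no support for that antibody. CX3CR1 stood at -0.48 (adjusted p = 0.0393) and Ly-6G, a neutrophil marker, at -0.59 (adjusted p = 0.0863, not called). Of 102 antibodies edgeR called 28, 14 higher and 14 lower. The split depends on the scaling, since the infiltrating cells carried more antibody counts (1750.2 and 1623 UMIs per cell, against 1313 and 1169): by UMIs per cell 67 were called (55 higher, 12 lower), and with isotype controls as library size 50 (17 higher, 33 lower). CD11b, CD49d, CD11a, CD38, CD9 and CX3CR1 were not called with classes by marker score. Over 43 antibodies whose gene had enough counts, the antibody and RNA log2 ratios had a Spearman correlation of 0.817 across genes, which are not independent replicates. Of the 43, 31 had the sign of their RNA, among them all 22 called ones.

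**Figure D3:**
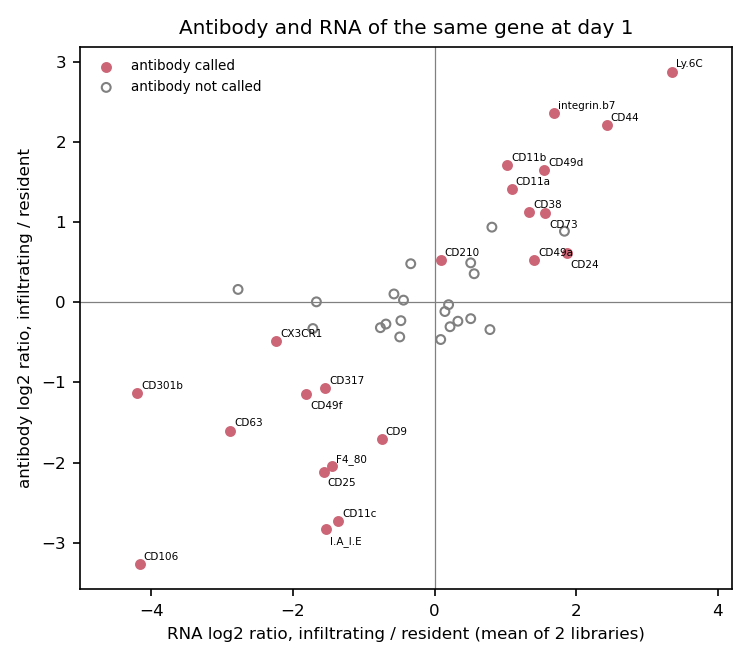
Antibody log2 ratio (vertical) against the RNA log2 ratio of the same gene (horizontal), infiltrating against resident-macrophage-like cells at day 1, with a point for each of 43 antibodies, filled where the antibody was called. CD106 and I-A/I-E lie at the lower left and Ly-6C at the upper right.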

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

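The tests of explanations below were chosen only after the results they bear on had been seen. Antibody signals appeared at day 1 on cells that the macrophage comparisons do not use, far above the level on the other cells. The lower of the ratios over the 2 libraries was 5.66 for CD3 on T-cell-like cells, 21.1 for NK1.1 on NK-cell-like cells and 49.2 for Ly-6G on neutrophil-like cells. Ly-6G was counted at 266 and 257 UMIs per neutrophil-like cell and at 5.40 and 2.70 on other cells. The classes were made from RNA alone.

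Long genes stood higher at day 1 than in quiescent cells. Across tested genes with a known span, which are not independent replicates, the Spearman correlation of span and log2 fold change was 0.454 in resident-macrophage-like and 0.385 in infiltrating cells, and -0.0577 and -0.0441 in the same classes at day 6. A candidate explanation is that reads over introns were counted in the day 1 matrices and not in the others. The average trend with span is not the whole cause of the calls, since 67.1% of the genes called in resident-macrophage-like cells at day 1 stayed called with the same sign after a correction for that trend. The correction removes only this average trend, so it cannot say how much intron reads add in single genes. Intron reads, time, gate, assay, batch and annotation stay open as sources of the rest.

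Arg1, Spp1 and Fn1 were higher in resident-macrophage-like cells at day 6 than in quiescent ones, but 95.4% of the Arg1 UMIs lay in the 38 cells of cluster 4. The 263 cells of cluster 11 held 2 and 3 Arg1 UMIs in day 6 libraries 2 and 3, too few to tell apart from free RNA in the droplets (lower 95% counting bound of UMIs per cell 0.0897 and 0.0838 times the upper bound of the lowest of cDC1-like, cDC2-like and nonclassical-monocyte-like cells). The values themselves were 0.0159 and 0.0219 UMIs per cell, against 0.00385 and 0.0365 in the lowest of those classes. Free RNA does not account for Arg1 in cluster 4, at 24.2 times or more in both libraries, nor do cells like the average infiltrating-macrophage-like ones placed there, since Arg1 needs a mixing share of 128% while Il1b (-13.1%), Osm (-2.14%) and Thbs1 (15.1%) stay far below and the lower quartile of 47 abundant transcripts is 4.82%, so that what these 38 cells are stays open. The cluster 4 cells are not the whole cause of the Spp1 and Fn1 rises, which were called within cluster 11 (1.85 and 3.85). The size of these rises moved both ways with the class border. Over 7 other class settings the log2 fold ran from 1.76 to 7.44 for Fn1 (4.29 with the clusters of all genes) and from 2.12 to 4.58 for Spp1 (3.35), so the border may be a source of the size. Within cluster 11 free RNA stays open for both, at 1.26 times or more for Spp1 and at 0.972 times in one library and 3.87 in the other for Fn1. Infiltrating-macrophage-like cells placed in cluster 11 stay open too, since Spp1 needs a share of 3.8% and Fn1 7.50%, Arg1 gives 0.527% and Il1b -9.57%, and the middle of all 47 shares ran from 2.05% to 16.9%, too wide to decide, as does a change within resident macrophages.

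Interferon response genes were lower at day 6 in all CD11b+ cells, with a list median of -1.39. By list medians, a shift between the classes as drawn does not account for this fall alone in infiltrating-macrophage-like, monocyte-like and cDC1-like cells. The median was -0.60 or lower in each of 6 classes or clusters tested alone. It was -0.62 in resident-macrophage-like cluster 11 (4 of 16 genes called lower) and -0.60 and -0.81 in classical-monocyte-like clusters 8 and 16 (0 of 14 and 0 of 12). In infiltrating-macrophage-like cells it was -1.68 (7 of 14), in nonclassical-monocyte-like -0.69 (2 of 10) and in cDC1-like cells -0.98 (3 of 9). The infiltrating-macrophage-like value rests on quiescent libraries 1 and 3, with 25 and 28 cells. A shift of cells within these classes was not tested. The smaller share of the interferon-led cluster 19 does not account for the fall alone either, since the median over all cells was -1.29 with that cluster left out. For cDC2-like cells a shift in the mix stays open, since the median was 0.31 within cluster 5, which held most of them in quiescent kidney, and -1.05 within cluster 7, which held most at day 6. Library batch cannot be told apart from the group, since quiescent and day 6 libraries share 0 batches. Injury itself, which the design names, may be the source and was not tested apart from batch.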

How the results depend on the processing

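The alternatives marked here as added (doublet score limit, gene span correction, single clusters, cluster 19 left out, clusters made without the naming genes) were chosen after seeing the data. Score classes were planned without a standardisation: it was first per library, and per gate replaced it after class counts had been seen, so that the per-gate classes, called score classes here, were not fixed beforehand. The other alternatives were. Of 340 values of 28 main results under an alternative, 259 kept their direction and their side of the threshold (for counts, within 1.5 times), 60 were lower, 19 higher, 2 moved and 0 turned. Of 11124 values of 539 pairs of named gene and comparison, over 8 comparisons, 10422 kept both, 587 lost and 71 gained a call and 44 turned sign. Another 132 values could not be had, Arg1 within cluster 11 among them, and neither could those of cycling-like cells with both score classes and with clusters made without the naming genes. Depth limits the small classes, with 313575 UMIs in the smallest library of cycling-like, 399333 of cDC1-like, 488509 of nonclassical-monocyte-like and 661033 of resident-macrophage-like cells. The cause of the changes below was not tested.

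Called genes in resident-macrophage-like cells at day 6 (300) numbered 189 by DESeq2, 608 with no low-count filter, 180 with stricter cells, 473 with doublets kept, 2660 with score classes, 705 with finer clusters, 2712 with the score per library and 584 (added) with clusters made without the naming genes. In infiltrating cells (1497) they numbered 323 with no filter, 628 thinned, 592 with the score per library, 36 (added) in classical-monocyte-like clusters and 477 (added) in infiltrating-macrophage-like clusters. All macrophages and monocytes gave 1415 with no filter. Nonclassical-monocyte-like cells gave 97 by DESeq2, 311 with no filter and 270 with score classes. Cycling-like cells gave 254 by DESeq2 and 375 thinned. cDC1-like cells gave 431 with no filter, 139 thinned, 111 with score classes, 126 with the score per library and 75 (added) without the naming genes, and cDC2-like cells 125 and 364 (added) in clusters 5 and 7. Thinning gave 3282 and 3208 for day 1 in resident-macrophage-like and infiltrating cells and 2380 for day 6 against day 1 in infiltrating cells. The difference between classes gave 17 with 10 CPM in 2 libraries. Called class shares (4) numbered 0 by the exact permutation test and 1 with the score per library, and the day 1 classical-monocyte-like share (17.9%) was 25.2% with doublets kept. With an estimated correlation 5 of 12 lists stayed called in resident-macrophage-like cells at day 6 (0 of 11 within cluster 11, added), 1 of 11 in the same class for day 6 against day 1, 2 of 9 in nonclassical-monocyte-like cells and 0 in the 10 other comparisons. fry called 10 lists in all cells and 15 in infiltrating cells for day 6 against day 1. Antibodies (28, 14 higher and 14 lower) numbered 67 (55 and 12) by UMIs per cell and 50 (17 and 33) with isotype controls.

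Leaving out each library in turn gave counts at day 6 of 50 to 578 (resident), 263 to 2405 (infiltrating), 478 to 3414 (all macrophages and monocytes), 201 to 4412 (all cells), 1099 to 3487 (cDC2), 30 to 485 (cDC1), 38 to 185 (nonclassical) and 262 to 894 (cycling). At day 1 it gave 3931 to 5150 and 4206 to 5986, and for day 6 against day 1 2668 to 3450 and 4525 to 4789 (resident and infiltrating). It gave 0 to 0 for the difference between classes and 1 to 7 class shares. Called lists ranged from 11 to 13, 15 to 17, 12 to 18 and 17 to 18 at day 6 (resident, infiltrating, combined, all cells), 10 to 13 and 10 to 15 at day 1, and 6 to 9 and 7 to 11 for day 6 against day 1.

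The samples share only a number across groups: deviations of samples with the same number correlated at -0.142 to 0.0748 over 2 shared numbers. A replicate block gave 554 called genes in resident-macrophage-like cells, 82 in cDC1-like and 310 in nonclassical-monocyte-like cells at day 6 and 4126 in infiltrating cells for day 6 against day 1. Of the class shares, mature-dendritic-cell-like cells stood at a log2 ratio of 1.40 (edgeR adjusted p = 0.0656, not called) and proximal-tubule-like cells at -1.70 (edgeR adjusted p = 0.0413, called) with the block.

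Named genes that turned sign, at day 6 in resident-macrophage-like cells, were Il1b (1.12 with doublets kept, 1.94 score, 1.26 finer, 0.26 coarser, 1.89 score per library, 1.13 without the naming genes), Ier2 (0.25, 0.48, 0.29, none coarser, 0.30, 0.24), Egr1 (0.50, 0.43, 0.58, none coarser, 0.18, 0.35) and Ifit3 (0.0663 coarser). In infiltrating-macrophage-like clusters alone (added), Cd177 (7.50), F13a1 (0.79), Gm1673 (0.18), Hdc (0.45), H2-DMb2 (-0.00025), H2-DMb1 (-0.79), Mmp14 (-0.0405), Igf1 (-0.65), Itgax (-0.86) and Cd81 (-0.95) turned against the combined class. In classical-monocyte-like clusters alone (added) P4ha1 (-0.091) and Ftl1 (-0.00966) did, and with the score per library H2-DMb2 (-0.53), H2-DMb1 (-0.20) and Top2a (-1.80). For day 6 against day 1 in resident-macrophage-like cells, score classes and the score per library turned Ifi204 (-0.31 and -0.44), Rtp4 (-0.24 and -0.55), Cxcl2 (0.92 and 0.98) and Itga4 (-0.19 and -0.21). The span correction (added) turned Adgre1 (-0.47) and Mrc1 (-0.0602) at day 1 in resident-macrophage-like cells and Adgre1 (0.60) for day 6 against day 1 in infiltrating cells, and clusters made without the naming genes H2-Eb1 (0.29) at day 1 in infiltrating cells. The cause was not tested for these genes.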

Other observations

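For these classes, counts of called genes and the gene lists were fixed before the data were examined. Naming single genes in them, by the rule fixed for the macrophage comparisons, went beyond that plan, and the tests within single cDC2-like clusters and with clusters made without the naming genes were chosen only after the results had been seen. cDC2-like cells, dendritic cells that present antigen to T cells, carried more lipid-associated and matrix transcripts at day 6 than in quiescent kidney, by lists not called with an estimated correlation. Of 13 lipid-associated genes 9 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 1.4e-11, re-estimated adjusted p = 0.0815). Of 12 matrix genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 8.2e-11, re-estimated adjusted p = 0.0815). Ccl17, a chemokine of dendritic cells that is among the genes leading cluster 7, rose from 27.0 ± 3.26 to 1331 ± 205 CPM (5.6 ± 0.14 on the log2 scale, edgeR adjusted p = 4.2e-07). Fabp5 (4.92), Fn1 (4.0), Apoe (3.07) and Itgax (0.82) rose, and Ifit2 (-3.41) and H2-Q7 (-2.44, uncertain beside its near-identical neighbour H2-Q6) fell. Of 14 oxidative phosphorylation genes 11 rose (11 adjusted over the list alone, camera adjusted p = 0.00015, re-estimated adjusted p = 0.209). Of 16 interferon response genes 10 fell and 1 rose (12 and 2 adjusted over the list alone, camera adjusted p = 0.00015, re-estimated adjusted p = 0.111). The interferon list median was 0.31 within cluster 5 and -1.05 within cluster 7, so its direction depends on the cluster. Tubule transcripts fell beside them in 7 of 11 and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0032, re-estimated adjusted p = 0.151), with Kap at -2.89. These cells lay mostly in cluster 5 in quiescent kidney (1762 cells) and in cluster 7 at day 6 (1332 cells). edgeR called 3151 of 10227 genes over the class, 125 within cluster 5 and 364 within cluster 7. The count over the class was 3098 with clusters made without the naming genes, and 1191 and 1099 without day 6 libraries 2 and 3.

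Nonclassical-monocyte-like cells, the patrolling monocytes, carried more Ccr2 at day 6 (392 ± 119 against 52.5 ± 13.9 CPM, 2.93 ± 0.21 on the log2 scale, edgeR adjusted p = 4e-06). Thbs1 (2.78), Spp1 (3.41) and Il1b (0.87) rose, and H2-K1 (-0.86) fell. Before TMM scaling, day 6 libraries 2 and 3 held 78.1 and 79.65 CPM of Spp1 there. Its level was 100 and 83.9 CPM in cDC1-like, 73.7 and 61.5 in cDC2-like and 2298 and 2503 in infiltrating-macrophage-like cells. Free RNA in the droplets is thus not told apart from a rise of Spp1 within nonclassical-monocyte-like cells. Of 4 matrix genes 3 rose (4 adjusted over the list alone, camera adjusted p = 2.2e-16, re-estimated adjusted p = 0.0407). edgeR called 168 of 6664 genes, 38 and 45 without day 6 libraries 2 and 3 and 270 with classes by marker score. In cDC1-like cells, which present antigen to cytotoxic T cells, Ifitm2 rose by 2.21 on the log2 scale, while Ly6a (-2.73), Trf (-2.33) and H2-K1 (-0.88) fell, and Mki67 was not called (0.18). edgeR called 212 of 6024 genes there, 60 without quiescent library 2, 485 without quiescent library 3, 30 and 53 without day 6 libraries 2 and 3 and 75 with clusters made without the naming genes. Cycling-like cells, a class that gathers dividing cells of several kinds, carried more Ctsl (4.88) and Trem2 (5.44) at day 6, with 11 of 12 lipid-associated genes higher (11 adjusted over the list alone, camera adjusted p = 2e-34, re-estimated adjusted p = 0.0543). edgeR called 682 of 6549 genes there, 438 without quiescent library 2, 329 and 262 without day 6 libraries 2 and 3 and 254 by DESeq2.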
